A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

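Okazaki fragments, the short DNA pieces made on the lagging strand at replication forks, were sequenced from 6 haploid strains of budding yeast in the W303 background, with 1 library per strain. Fragments accumulate when Cdc9, the DNA ligase that joins them, is depleted. Per the labels' protocols, the 3 strains of the chrVI set carried Cdc9 that can be moved out of the nucleus (anchor-away) and received rapamycin at 1 µg/mL for 1 h. The 3 strains of the chrX set carried CDC9 under a promoter that doxycycline turns off, and received 40 mg/L for 2 h. Each set held a control strain with the Flex1 control cassette, a strain with 34 AT/TA repeat units, written (AT)34, and an (AT)34 strain in which RAD52 is given as deleted. The cassette lay at an integration site of chromosome VI, or 2 kb from the origin ARS1019 on chromosome X. All 6 libraries carry the same batch label, so a batch could not be tested.

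The deposited values were coverage, a signal of whole numbers per base and strand, with no normalization in them, per the file headers and from the values. BWA 0.7.17, SAMtools 1.19 and the genome build R64 are named in the submitters' processing notes. Read filters, the handling of duplicate reads and what was merged before deposit were not given in the sources used here. A read covers many neighbouring bases, so coverage is not a count of reads and no counting interval could be given. Rises in coverage were most strongly followed by falls 76 bp later, and 51 bp later in the chrX control, so the reads of that library were shorter.

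Everything below was computed from these coverage values with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. Mean coverage of the 12071327 nuclear bases lay between 25.5 and 42.9 per library, and 4.54 to 4.95% of bases were uncovered. Plus-strand over minus-strand totals lay between 1.03 and 1.05. Plus-strand coverage was taken as the product of leftward forks, which was checked at 4 known origins. Fork direction was (rightward minus leftward coverage) over their sum, from +1 for all rightward to −1 for all leftward forks.

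At the insertion site, fork direction was taken over 5 kb on each side, leaving out 250 bp next to it, and the 95% interval came from 1000 draws of blocks of 200 bp. These intervals cover sampling along the window only. Differences between libraries of a set were placed among positions on a 1 kb grid whose control value lay within 0.2 of the site, leaving out 20 kb at chromosome ends, the rDNA and 20 kb around the insertion. Coverage at the site was taken over 1 kb on each side, against the library's median bin. With 1 library per strain, no test was possible there. On chromosome VI the labels give a locus name without coordinates, so an insertion was searched as a narrow coverage dip of up to 300 bp shared by the libraries of a set. None stood clear, and the whole chromosome was scanned.

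Origins were called from the mean profile of the 6 libraries as places where the leftward share in the 10 kb to the left exceeded that in the 10 kb to the right by at least 0.05, at least 10 kb apart. This difference of shares was the origin efficiency. It gave 282 origins, of which 281 lay over 20 kb from the chrX site and were tested. Named origin classes that need an annotation of origins were not analysed here, nor were centromere, long terminal repeat and natural AT/TA repeat lists, which need an annotation or a genome sequence. The landmark origins were placed by the genes beside them, from general knowledge.

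Gene coverage was the mean over the coding region, relative to the library's median gene, as log2(value + 0.05). Differences of low genes are understated on this scale. Genes and coordinates came from a RefSeq gene table of the same build, in which 6002 nuclear protein-coding genes were found. Of these, 5958 were tested and 44 were covered in no library. Origins and genes were tested with limma (trend and robust, chromosome set plus strain type, 2 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. The strain with the same construct in the other set acted as its replicate, and nothing in the labels says that cultures were repeated, so p-values measure the spread between these libraries only. In the origin fit limma took each origin's spread from the fitted trend alone. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. The classes of histone, glycolysis, ribosomal protein and telomere-proximal genes were set before the data were examined. The members of every list, and the recombination and the replication and ligation lists, were written afterwards from general knowledge. For lists of genomic features without replicates, the median was placed among 10000 random lists of the same size matched on coverage.

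The rule for named items, also set before the data were examined, took the engineered genes, the genes and origins next to the insertion, and the 5 largest regions of each comparison within a set, ranked by the median of the fork direction differences in a 1 kb bin and its 2 neighbours. It also took the 10 origins, or the 10 genes in each direction, with the largest change among those past the threshold and changed the same way in both sets or in all 3 strain types. Where fewer origins passed, it took the 5 with the smallest p. Members of the lists that are named beside their list's result were chosen after their values were seen. The gene comparison of (AT)34 with control strains was not planned.

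Alternatives covered window lengths, gaps, averaging, low-coverage filters, strand balance, capping, position shifts, the pseudocount, quantile and total-coverage scaling, the options of limma, and leaving out each library in turn. A common amplitude of fork direction, the left side of ARS1019 and the 5 kb to the right of the site alone were added after the data had been seen.

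The steps were tested on simulated data. Among 20 origins each changed by 0.1, 0.2 and 0.4, limma recovered 10.0, 70.0 and 100.0% for the RAD52 comparison and 5.0, 80.0 and 100.0% for the set comparison. Among 67, 67 and 66 genes changed by 0.5, 1.0 and 2.0 on the log2 scale, it recovered 26.9, 95.5 and 100.0% for the RAD52 comparison and 49.3, 97.0 and 98.5% for the set comparison. Of the 164 and 172 genes called, 16 and 9 had not been changed, and of the 37 origins called in each comparison 1 and 0 had not. For the RAD52 comparison each change was put into both libraries with that label, with independent noise. The recovered shares therefore do not hold for a change present in only 1 of them. Simulated efficiencies of 0.2, 0.5 and 0.8 came out at 0.201, 0.496 and 0.798. Simulated fork direction differences of 0, 0.1 and 0.2 lay inside their intervals in 93, 90 and 94 of 100 runs.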

Results

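Replication fork direction and Okazaki fragment coverage were measured in 6 yeast libraries, 1 each for a control strain, an (AT)34 strain and an (AT)34 strain given as lacking RAD52, with the insertion on chromosome VI or on chromosome X. The series asks how cells process AT/TA repeats that can fold into cruciforms, and the libraries address whether forks behave differently at the repeat and elsewhere. Mean coverage per base was 25.5 in the chrVI control, 35.7 in chrVI (AT)34 and 31.5 in chrVI (AT)34 rad52Δ. It was 42.9 in the chrX control, 34.7 in chrX (AT)34 and 32.7 in the library labelled rad52Δ (AT)34 chrX. No strain had a replicate, so values at single loci have no error between cultures.

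RAD52, the main mediator of homologous recombination in yeast (chromosome XIII, 212515 to 213930, R64), was lost in the library of the chrVI set that is labelled as its deletion. Its coverage there was 0.0046 of the median gene (95% interval 0.0011 to 0.0082), and 88.4% of its coding bases were uncovered. In the library labelled rad52Δ (AT)34 chrX, RAD52 was covered at 1.10 (0.856 to 1.42) with 0% of bases uncovered, against 1.12 to 1.22 in the 4 RAD52+ libraries. The data thus went against that label, although an insertion that leaves the coding sequence in place would not show as lost coverage. The region around RAD52, 202.5 to 218.5 kb, had a fork direction of −0.253 in this library, against 0.425 to 0.584 in the others. The segment beside it, between Ty elements, had 1.65 times the coverage of the next, against 0.872 to 0.955 in the others. Whether the locus was changed in a way that keeps RAD52 covered was not tested. FPR1, the rapamycin-binding protein deleted for anchor-away, stood at 0.0386, 0.0551 and 0.0407 in the chrVI control, (AT)34 rad52Δ and (AT)34 libraries. It lay between 1.05 and 1.34 in the chrX set. In the 500 bp upstream of CDC9, where the chrX set carries the doxycycline promoter, 7.8 to 8.0% of bases were uncovered in the chrX set and 0% in the chrVI set.

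Among the marker genes, LEU2 stood at 2.50 in chrVI (AT)34 rad52Δ and between 1.37 and 1.79 in the other libraries. TRP1, a marker of the anchor-away strains, stood at 3.56, 3.61 and 2.54 in the chrVI control, (AT)34 and rad52Δ libraries, and at 1.32, 1.72 and 2.52 in their chrX counterparts. HIS3 lay between 0.27 and 0.48 in the chrVI set and between 0.62 and 1.2 in the chrX set. CDC9 itself lay between 0.391 and 0.575 in the chrVI set and between 0.622 and 0.758 in the chrX set. TOR1 lay between 1.35 and 1.60, RPL13A between 0.606 and 0.833, URA3 between 2.03 and 2.53, ADE2 between 0.591 and 1.33 and CAN1 between 1.09 and 1.25.

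At 4 well-known origins, forks left in both directions in every library. The plus-strand share was higher on the left than on the right of ARS607 next to PES4, ARS606 next to DCV1, ARS416 next to TRP1 and ARS1019 in JJJ3, by at least 0.582. Fork direction profiles in 1 kb bins correlated across bins at 0.971 to 0.988 in the 6 pairs within a set and at 0.947 to 0.975 in the 9 pairs between sets. The lowest value, between the chrVI control and the library labelled rad52Δ (AT)34 chrX, had a 95% interval of 0.940 to 0.954. Bins of 2 libraries are not replicates, so these values only describe the libraries.

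On chromosome VI without its outer 20 kb, the largest fork direction differences of the chrVI set ranked below those of most other chromosomes. The largest difference between chrVI (AT)34 and its control was −0.174 (95% interval −0.232 to −0.0971) at 118 kb in CDC4, a subunit of the SCF ubiquitin ligase, beside the called origin at position 118401. Of the largest differences on each of the 16 chromosomes, it ranked at 13. Between chrVI (AT)34 rad52Δ and chrVI (AT)34, the largest difference was 0.347 (0.269 to 0.425) at 74 kb in RIM15, a protein kinase of the nutrient response, and ranked at 11. Against the control the same place in RIM15 differed by 0.431 (0.347 to 0.511), at rank 10. The places in CDC4 and RIM15 were picked as the largest differences of the scan, so their intervals do not test for a difference. Among all scanned positions of the genome, these differences were larger than 97.6, 99.1 and 99.4%. For (AT)34 minus control, 222 positions were scanned on chromosome VI and 1468 on chromosome IV. A short chromosome ranks high less easily, so the ranks do not show that no difference was present. In the end left out of this scan, the bins from 6 to 20 kb lay between −0.890 and −0.130 in chrVI (AT)34 rad52Δ, lower in each bin than in (AT)34 (−0.270 to 0.898) and the control (−0.0616 to 0.630), and some of these differences were larger than that at RIM15. With windows of 10 kb the differences at RIM15 were 0.198 and 0.281, and with the mean of 100 bp values the difference in CDC4 turned to 0.0167. The position of the insertion was not found. The strongest shared coverage dips of the chrVI set, at 92330 in BUD27 and at 162161 between FAR7 and GCN20, scored 0.83 and 0.81 on the log2 scale and did not stand apart. A known change, the tagged 3′ end of CDC9, scored 0.36, below the dips found elsewhere, so the search could not have placed an insertion.

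**Figure D1:**
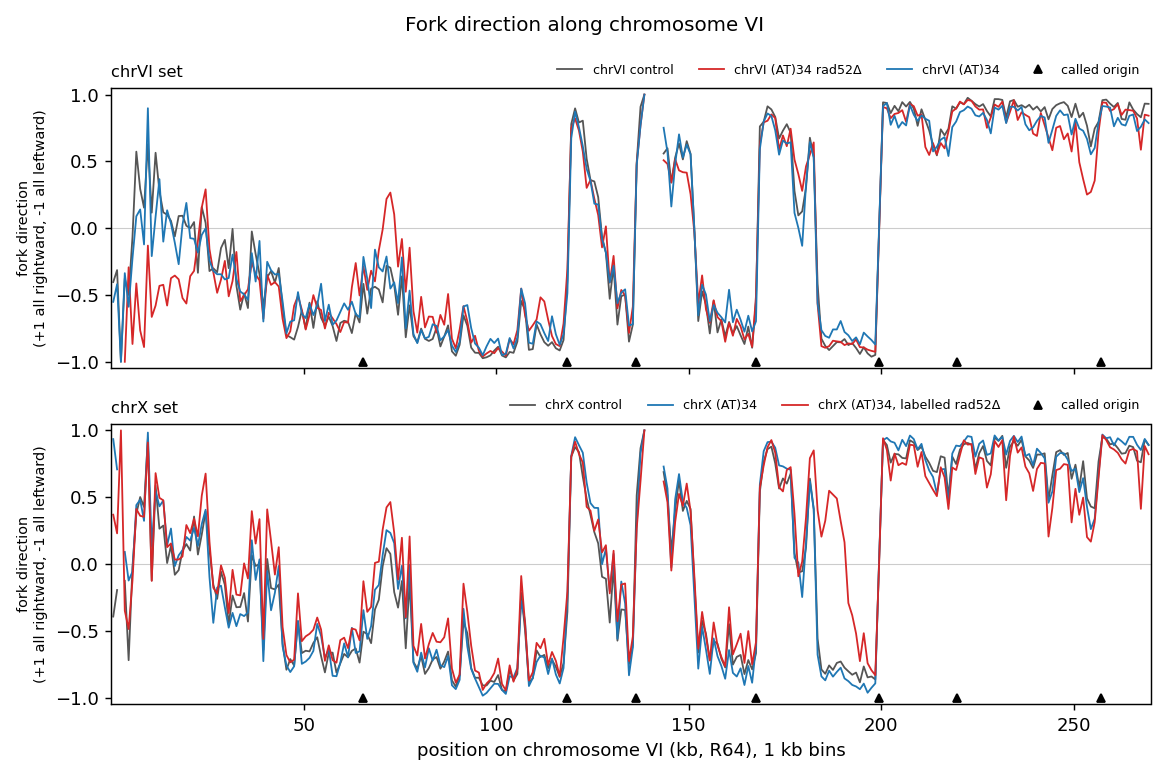
Fork direction (+1 all rightward, −1 all leftward) in 1 kb bins against position on chromosome VI in kb, with a line per library, the chrVI set above and the chrX set below, and triangles at called origins. The lines of a set overlie each other over most of the chromosome, and the line labelled rad52Δ in the chrX set turns rightward between 182.5 and 191.5 kb.

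On chromosome X, the labels place the insertion 2 kb from ARS1019 without giving the side. The place 2 kb to its right, in YJR098C (position 614801), was taken as the site. The window of 5 kb on each side spans ARS1019 and so mixes its leftward with its rightward forks. Fork direction over it was 0.304 in the chrX control, 0.340 in chrX (AT)34 and 0.262 in the library labelled rad52Δ (AT)34 chrX. In the chrVI set, which has no insertion there, it was 0.327 in the control, 0.258 in (AT)34 and 0.318 in (AT)34 rad52Δ. The repeat library exceeded its control by 0.0367 (95% interval −0.0096 to 0.0850), which is larger in size than 32.0% of 1856 matched positions. The library labelled rad52Δ, in which RAD52 was covered, lay −0.0779 from (AT)34 (−0.129 to −0.0184), larger than 59.1% of matched positions, and −0.0412 from the control (−0.0931 to 0.0160), larger than 36.6%. In the 5 kb to the right of the site only, a window added after the data had been seen that leaves out the origin, forks ran rightward at 0.844 in the chrX control, 0.894 in (AT)34 and 0.768 in the library labelled rad52Δ. The differences there were 0.0499 from control to (AT)34, −0.126 from (AT)34 to the labelled library and −0.0758 from control to it, larger than 62.8, 85.5 and 75.4% of matched positions. Neither repeat library left the range that these libraries show elsewhere in the genome. On the other side of ARS1019, the side that the labels do not settle, the difference between the library labelled rad52Δ and (AT)34 was 0.0062, and that from the control 0.0296. At the site itself, windows of 2 kb put the library labelled rad52Δ −0.104 from the control.

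**Figure D2:**
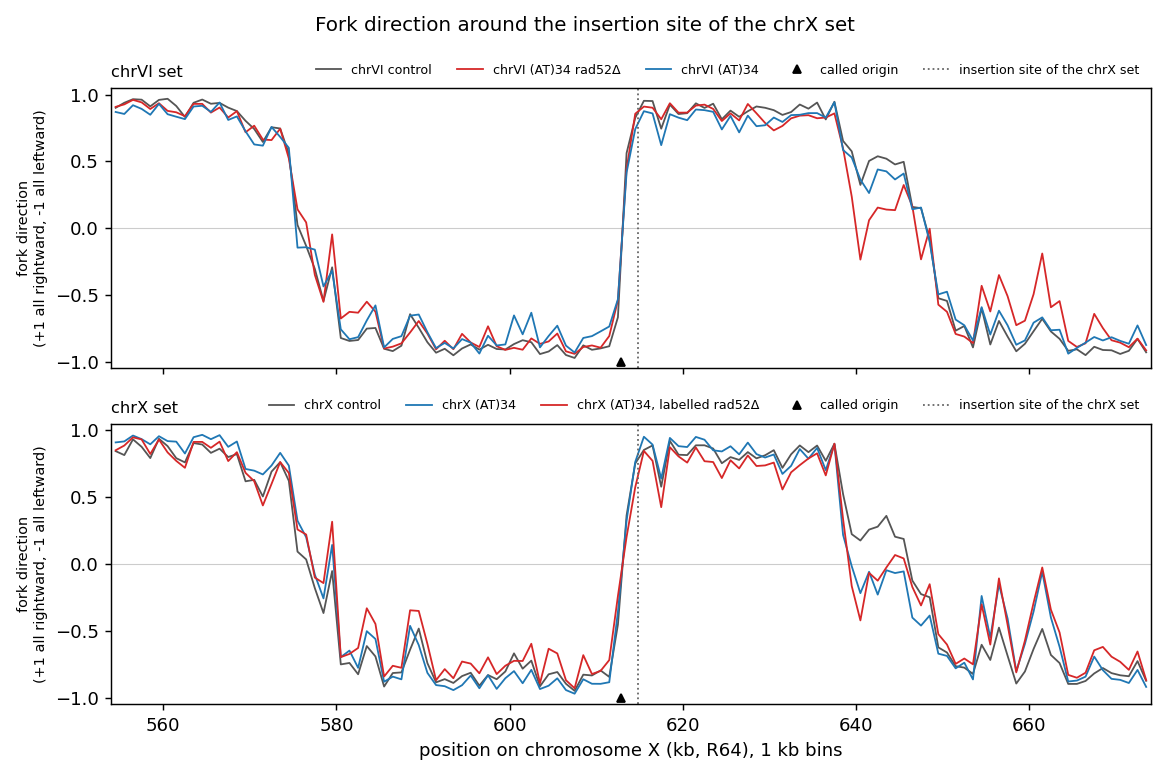
Fork direction (+1 all rightward, −1 all leftward) in 1 kb bins against position on chromosome X in kb around ARS1019 (triangle), with a line per library, the chrVI set above and the chrX set below. The dotted line marks the place taken as the insertion site of the chrX set, to the right of ARS1019, a side that the labels do not give. All lines turn from leftward to rightward forks at ARS1019, and in the 5 kb to the right of the site they lie at 0.768 to 0.894 in the chrX set.

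ARS1019, in JJJ3 at 612801, was among the efficient origins in every library. Its efficiency was 0.832 in the chrX control, 0.866 in chrX (AT)34 and 0.763 in the library labelled rad52Δ, against 0.881, 0.809 and 0.852 in the control, (AT)34 and rad52Δ libraries of the chrVI set. Its neighbours, at 540601 between HIT1 and YJR056C and at 684001 between MET5 and IML1, had mean efficiencies of 0.844 and 0.890. Coverage within 1 kb of the site stood at −0.26, −0.02 and −0.29 (log2 of the median bin) in the chrX control, (AT)34 and the library labelled rad52Δ. In the chrVI set it was 0.70, 0.50 and 0.44 in the same order. The (AT)34 library lay 0.23 above its control (0.08 to 0.35), a size larger than 83.0% of genomic positions. The library labelled rad52Δ lay −0.26 from (AT)34 (−0.39 to −0.16), larger than 87.4%, and −0.03 from the control, larger than 16.9%.

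Across the genome, no origin passed for the RAD52 label. The origins with the smallest p, none of which passed, were a weak origin in MSO1 (XIV 713601, 0.110), the origin between YCR090C and KIN82 (III 273701, 0.205, SE 0.0646), that between MAL33 and MAL31 (II 802201, −0.125), that between PPQ1 and CBC2 (XVI 210301, 0.130) and that in YCT1 (XII 31401, 0.0807). Values are the library with the RAD52 deletion label minus (AT)34, averaged over both sets. At the origin beside KIN82 the difference was 0.401 in the chrVI set and 0.0082 in the chrX set, where the library labelled rad52Δ had RAD52 covered. The smallest adjusted p from limma was 0.274, and 12 of 281 origins had an unadjusted p under 0.05. Without chrVI (AT)34, 102 origins were called, all lower; without chrX (AT)34, 22 were called, 21 of them higher; without the library labelled rad52Δ (AT)34 chrX, 7 were called, all higher. In these fits 1 strain type holds a single library and the others supply its spread, so the calls show no effect of the label.

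For the repeat, no origin passed either. The smallest p values, none of which passed, belonged to origins between CDC15 and PAU7 (I 176801, −0.154), in MRS3 (X 161501, 0.131), between PPQ1 and CBC2 (XVI 210301, −0.0915), in MDM12 (XV 309501, 0.0605) and between PAM16 and GSM1 (X 228901, 0.107). At the origin beside CDC15 the difference was −0.340 in the chrVI set and 0.0319 in the chrX set. The 10 kb to its left include part of the region around ADE1, 165.5 to 170.5 kb, where fork direction turned in chrVI (AT)34 only. Its value is therefore not separate from that change. The smallest adjusted p from limma was 0.999, and 1 origin had an unadjusted p under 0.05. Without chrVI (AT)34, 39 origins were called, all higher; without chrX (AT)34, 83 were called, 82 of them lower. The 7 origins of chromosome VI, the 14 of chromosome X and the 14 within 30 kb of a chromosome end had median differences of −0.0016, −0.0085 and −0.00079 for the repeat and −0.0241, −0.0108 and 0.0130 for the RAD52 label, and camera called none of these classes for the repeat, the RAD52 label or the chromosome set.

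Many weak origins were more efficient in the chrX set than in the chrVI set. The largest change was at the origin in MTC2 (XI 257701), with efficiencies of 0.598, 0.624 and 0.610 in the chrX control, (AT)34 and library labelled rad52Δ, against 0.165, 0.169 and 0.372 in their counterparts of the chrVI set (difference 0.375, SE 0.0549, limma adjusted p = 2.96e-09). Origins in UGA4 (IV 85801, 0.247), between YIL102C and XBP1 (IX 174901, 0.244), in ANS1 (VIII 359901, 0.235), beside FKH2 (XIV 498701, 0.221) and in MGL2 (XIII 688801, 0.209) rose as well. So did the one beside PEP8 (X 337201, 0.197) and 2 with mean efficiencies of 0.502 and 0.614, between CHS1 and DUG3 (XIV 280001, 0.209) and in YKL183C-A (XI 98501, 0.203). The origin between MAL33 and MAL31, near the right end of chromosome II, fell (−0.199, SE 0.0382, limma adjusted p = 1.73e-05). Of the 127 tested origins with a mean efficiency of 0.5 or less, 54 passed as higher in the chrX set and 2 as lower, and the median difference of all 127 was 0.0785. Of the 154 more efficient ones, 7 passed as higher and 1 as lower, and the median of all was −0.0117. In the 127 weaker origins the median efficiency was 0.125, 0.135 and 0.205 in the chrVI control, (AT)34 and rad52Δ libraries. It was 0.222, 0.259 and 0.269 in their chrX counterparts, so chrVI (AT)34 rad52Δ lay near the chrX control.

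In all, 64 origins passed between the sets in limma, 61 higher and 3 lower in the chrX set. The sets differ in Cdc9 depletion, drug and strain construction together, which cannot be told apart. Leaving out the chrVI control gave 0 origins (28 at an unadjusted p under 0.05) and leaving out the chrX control gave 1. Without chrVI (AT)34 there were 49 higher and 81 lower, and without chrX (AT)34 there were 47 higher and 83 lower. On a logit scale 15 passed, and with fork direction at a common amplitude, an alternative added after the data had been seen, 132 passed.

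**Figure D3:**
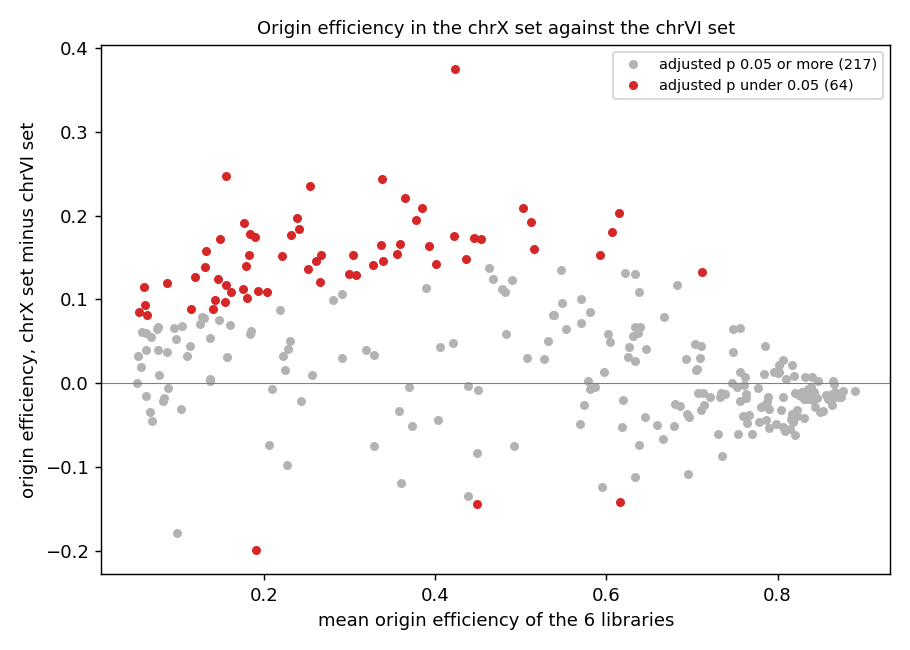
Difference in origin efficiency between the chrX set and the chrVI set (vertical) against the mean efficiency of the 6 libraries (horizontal), with a point per tested origin and red points for the 64 with a limma adjusted p under 0.05. The red points lie mostly above 0 and at mean efficiencies of 0.5 or less, where 54 origins passed as higher and 2 as lower.

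Coverage of few genes followed the RAD52 label. BRP1, a short open reading frame in the promoter region of PMA1 (VII 483260 to 483637), fell by 0.82 on the log2 scale (SE 0.15, limma adjusted p = 0.0019). MEO1 (II 490850 to 491056) fell by 0.77 (adjusted p = 0.0051). BRP1 stood at 0.745 and 0.749 in the 2 libraries with that label and at 1.01 to 1.53 in the other 4. RAD52 itself, lost in only 1 of the 2, had an estimate of −2.28 and did not pass (adjusted p = 0.817). Of 5958 genes, 432 had an unadjusted p under 0.05. Quantile scaling gave 0 genes (289 at an unadjusted p under 0.05), omission of chrVI (AT)34 rad52Δ 0 (44 at an unadjusted p under 0.05) and omission of chrX (AT)34 277. Without the library labelled rad52Δ (AT)34 chrX, BRP1 and MEO1 kept their direction but were not called again. Fits without 1 library leave a strain type with a single library, so their counts of calls show no effect of the label.

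For the repeat, HMRA1, the a1 gene of the silent mating cassette HMR (III 293835 to 294321), rose by 1.13 (SE 0.21, limma adjusted p = 0.00065). Its coverage was 0.358 and 0.444 in the controls and 0.686 to 1.08 in the repeat libraries. VBA5, a plasma membrane transporter gene near the right end of chromosome XI, rose by 1.00 from levels of 0.0109 and 0.0792 in the controls, close to the pseudocount. The short reading frames YOL155W-A and YHR213W-B rose by 1.60 and 0.68. YGR164W fell by 0.73, and YLR154C-G, which lies in the repeated rDNA, fell by 0.63. HMRA1 and YLR154C-G have sequence copies elsewhere in the genome, and how such reads were placed was not given. These 6 were all that passed, and 109 genes had an unadjusted p under 0.05. With quantile scaling (73 at an unadjusted p under 0.05), without chrVI (AT)34 rad52Δ (94 at an unadjusted p under 0.05) and without the library labelled rad52Δ (AT)34 chrX (92), 0 passed. Without chrX (AT)34 52 passed, without chrVI (AT)34 27, without the chrX control 17 and without the chrVI control 9.

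Between the sets, coverage of many genes differed. FPR1 (XIV 371882 to 372226), deleted in the chrVI set, was 3.68 higher in the chrX set on the log2 scale (SE 0.24, limma adjusted p = 4.58e-25). Next came IES4, a subunit of the INO80 chromatin remodeler (1.52, SE 0.15), COQ21 (1.41), YLR379W-A (1.41) and PEX22, a peroxisome biogenesis gene (1.33). TAE1 (1.30), PXR1 (1.29), YPT10 (1.29), the tropomyosin gene TPM1 (1.28) and RPC19, a subunit of RNA polymerases I and III (1.25), followed. The largest decreases were in BUD16 (−0.97, SE 0.12), ECM9 (−0.93), YOR011W-A (−0.87), YIL001W (−0.85), the adenine gene ADE1 (−0.83) and YEA6 (−0.82). TRP1 (−0.82), DFP1 (−0.82), the splicing gene PRP39 (−0.81) and the histone gene HTB2 (−0.81) came next. ADE1 and TRP1 were also uneven within the chrVI set, with ADE1 at 4.90 in (AT)34, 2.28 in rad52Δ and 1.70 in the control.

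In total 2093 of 5958 genes passed between the sets, 1341 higher and 752 lower in the chrX set. With quantile scaling 1532 passed, 757 higher and 775 lower; 1239 of the 2093 were among them, and all 2093 kept their direction. Fewer passed without the chrX control (808), the chrVI control (827), the library labelled rad52Δ (1165) or chrVI (AT)34 rad52Δ (1188). YJR098C, at the place taken as the chrX site, and JJJ3, at ARS1019, were lower in the chrX set by −0.58 and −0.40 (limma adjusted p = 9.5e-05 and 0.018). The labels do not give the side of ARS1019, and YJR098C is at the site only if the insertion lies to the right.

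Histone genes were lower in the chrX set, but the call of the list rested on camera's preset correlation. All 8 had negative differences and 6 passed, HTB2 (−0.81), HTA2 (−0.77), HTB1 (−0.68), HHT1 (−0.59), HHF1 (−0.55) and HTA1 (−0.49), while HHT2 (−0.31) and HHF2 (−0.13) did not. Adjusted over the list alone 7 passed. The list median was −0.57, and −0.55 with quantile scaling (camera adjusted p = 0.00012, and adjusted p = 0.726 with an estimated correlation). Genes within 20 kb of a chromosome end were higher, with 78 of 215 passing, none of them lower, and 80 adjusted over the list alone. With quantile scaling 27 passed as higher and 7 as lower. VEL1 (1.14), the alcohol dehydrogenase gene ADH4 (1.11) and AGP3 (1.11) were the largest. The list median was 0.26, and 0.09 with quantile scaling (camera adjusted p = 9.6e-05, and adjusted p = 0.447 with an estimated correlation). Of the 215 genes, 164 had positive differences. A like shift was seen in the 1944 genes over 30 kb from an origin with an efficiency over 0.5, with 1468 higher and a median of 0.23. Whether the list differed from those genes was not tested.

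The other lists were not called between the sets, and their balance moved with the scaling. Of 18 glycolysis genes 5 passed as higher, among them HXK2 (0.96), ENO1 (0.95) and PFK1 (0.80), and 2 lower, TPI1 (−0.46) and PDC1 (−0.43), with 7 adjusted over the list alone, and 4 and 1 with quantile scaling. Of 17 recombination genes, RAD50 (1.06), MUS81 (0.66), MRE11 (0.59) and SLX1 (0.42) were higher and RAD57 (−0.54) lower, 5 adjusted over the list alone, and 2 and 2 with quantile scaling. Of 15 replication and ligation genes 5 passed as higher and 0 as lower, POL2 (0.61), POL1 (0.59), CDC9 (0.51), RAD27 (0.41) and TOF1 (0.35), with 4 adjusted over the list alone, and 2 and 2 with quantile scaling. Of 137 ribosomal protein genes 63 had positive and 74 negative differences, and 19 passed as higher, such as RPS29A (1.12), and 9 as lower, such as RPL14B (−0.50), with 25 adjusted over the list alone. With quantile scaling 8 passed as higher and 25 as lower, the opposite balance. Among 9 genes of the engineered loci, FPR1 (3.68), HIS3 (1.12) and ADE2 (0.68) were higher and TRP1 (−0.82) lower, 5 adjusted over the list alone, and 2 and 2 with quantile scaling.

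For the RAD52 label, glycolysis genes lay lower as a list. Of the 18, 14 had negative estimates, led by TPI1 (−0.53) and PDC1 (−0.53), with a median of −0.14; 0 passed over all genes and 1 adjusted over the list alone. Its camera adjusted p was 0.0458, and adjusted p = 0.622 with an estimated correlation. The call ended with quantile scaling (0.0611) and without the library labelled rad52Δ (AT)34 chrX (0.158). For the repeat, genes within 20 kb of a chromosome end lay higher, 152 of 215 with a median of 0.11, against 0.03 over all genes. Only VBA5 passed, and 10 adjusted over the list alone. The camera adjusted p was 2.17e-09, and adjusted p = 0.224 with an estimated correlation, and quantile scaling ended the call (0.0596). Recombination genes had 1 gene adjusted over the list alone for the RAD52 label, and the lists not mentioned for these contrasts had 0.

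Transfer RNA genes, known places of fork pausing, stood apart in chrVI (AT)34. Coverage of the 273 genes over their flanks had a median of −0.44 (log2) there, against −0.16 in the chrVI control and −0.19 in chrVI (AT)34 rad52Δ. The median difference from the control was −0.29, outside the range of −0.06 to 0.02 that holds 95% of random lists. The absolute fork direction at these genes was 0.715 in chrVI (AT)34 and 0.832 in the control, with a median difference of −0.0862, outside −0.0790 to −0.0521. In the chrX set the difference between (AT)34 and control was 0.02, inside the range, and that between the library labelled rad52Δ and (AT)34 was −0.09, outside it. The random lists were not matched on sequence copies, and how reads of repeated sequence were placed was not given. Library chrVI (AT)34 also had the lowest coverage of the rDNA and the CUP1 array, 2.21 and 0.257 of the median. A change in fork pausing at tRNA genes therefore cannot be told apart from a difference in coverage of repeated sequence. Ribosomal protein genes were higher in chrVI (AT)34 rad52Δ than in chrVI (AT)34 by 0.15 and in chrX (AT)34 than in its control by 0.05. In all, 9 of 64 list medians lay outside the range. The others were replication and ligation genes (0.20), telomere-proximal genes (−0.02) and tRNA genes (0.24) between rad52Δ and (AT)34 of the chrVI set, and engineered loci (0.13) between their chrX counterparts. With flanks of 1 to 3 kb the replication and ligation genes, the ribosomal protein genes of chrX (AT)34 and the engineered loci lay inside the range.

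The largest fork direction differences within a set are given as the median over a 1 kb bin and its 2 neighbours, and the values of single libraries as those of the bin itself. In chrVI (AT)34, forks ran rightward between BUD14 and ADE1 (I 169 kb, 0.606) against −0.720 to −0.559 in the other libraries, a difference of 1.20 for (AT)34 minus control and of −1.33 for rad52Δ minus (AT)34. The next differences were at 29 kb on chromosome XII beside YCT1 (0.940 and −0.925), RTG3 (II 23 kb, −0.857), YHK8 (VIII 205 kb, −0.536) and KRE5 (XV 952 kb, −0.432). In RTG3 chrVI (AT)34 and rad52Δ stood at −0.892 and −0.856, the chrVI control at −0.0344 and the chrX libraries at −0.332 to −0.284. Beside YCT1 chrVI (AT)34 stood at 0.201, its control and rad52Δ at −0.534 and −0.564, and the chrX libraries at −0.183 to 0.0404. In KRE5 the chrVI control was the one that stood apart, at 0.414 against 0.0420 to 0.180. In chrVI (AT)34 rad52Δ, the bin between HMRA1 and GIT1 (III 295 kb) differed by 0.923 from (AT)34, FIG2 (III 271 kb) by −0.762 and HXT8 (X 27 kb) by 0.663. In FIG2 and HXT8 its values of −0.672 and 0.215 lay within those of the chrX set, −0.772 to −0.475 and 0.0661 to 0.481. The largest differences of chrX (AT)34 from its control were at IMO32 and NAG1 (VII 547 kb, −0.484), between IME2 and SET4 (X 224 kb, −0.481), RPN1 (VIII 162 kb, −0.480), beside HXT8 (X 29 kb, −0.447) and between TDA4 and STE24 (X 642 kb, −0.438). In the scan of each chromosome with windows of 5 kb, chromosome X ranked at 1 for this comparison, with 0.452 at 30 kb beside HXT8, over 500 kb from the insertion site. It ranked at 12 and 8 for the library labelled rad52Δ minus (AT)34 and minus control. Between TDA4 and STE24, the nearest of these regions to the site, the chrX control stood at 0.387, (AT)34 at −0.120 and the library labelled rad52Δ at −0.0046, while chrVI (AT)34 rad52Δ, without the insertion there, stood at 0.150.

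In the library labelled rad52Δ (AT)34 chrX, forks in FAB1, the kinase that makes phosphatidylinositol bisphosphate on the vacuole (VI 187 kb), ran rightward at 0.542 and leftward at −0.881 to −0.765 in all others. Its difference from chrX (AT)34, as the median over the bin and its 2 neighbours, was 1.30. YMD8 (XIII 204 kb) followed with −0.787, then the bin between RRT15 and MAS1 beside the rDNA (XII 491 kb, 0.734), YHK8 (VIII 206 kb, −0.715) and PEX6 (XIV 21 kb, 0.496). The YMD8 region, 202.5 to 218.5 kb, includes RAD52, and its fork direction was −0.253 in this library against 0.425 to 0.584 in the others. These differences compare libraries, not genotypes, and RAD52 was covered in this library.

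**Figure D4:**
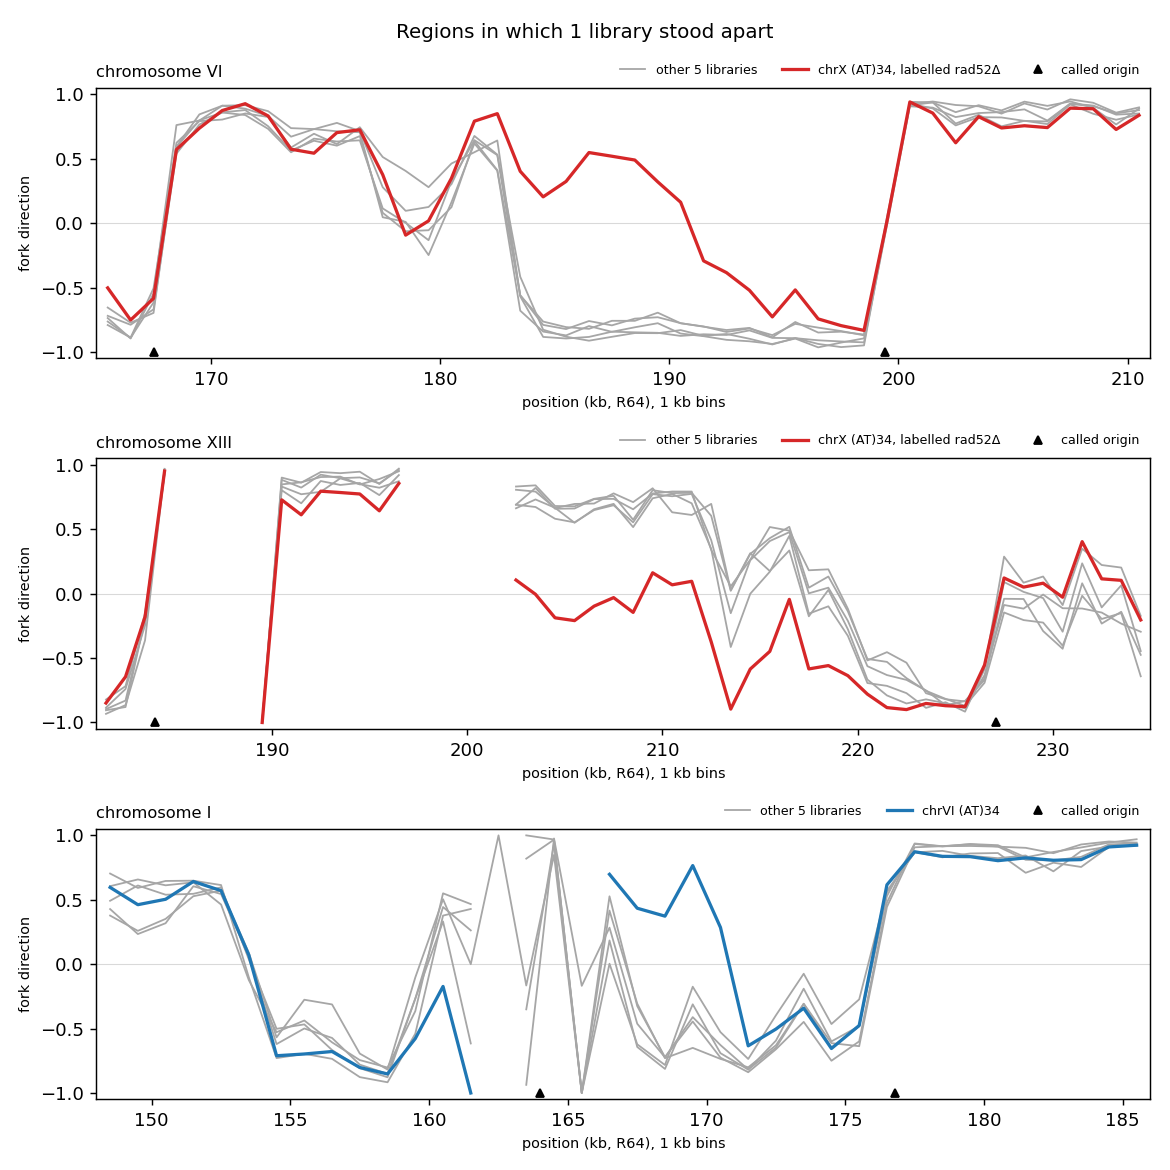
Fork direction (+1 all rightward, −1 all leftward) in 1 kb bins against position in kb in regions of chromosomes VI, XIII and I, with the library that stood apart in colour, the other 5 in grey and triangles at called origins; bins with too little coverage are blank. On chromosome VI between 182.5 and 191.5 kb the coloured library has a fork direction of 0.370 against −0.764 to −0.655, and on chromosome I between 165.5 and 170.5 kb it has 0.620 against −0.520 to −0.347.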

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

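All tests in this part were chosen after the results had been seen.

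From control to (AT)34, origin efficiency changed by a median over origins of −0.0457 in the chrVI set, with 231 of 282 origins lower, and by 0.0397 in the chrX set, with 241 higher, opposite directions whose difference was not tested. From (AT)34 to the library with the RAD52 deletion label the median change per origin was 0.0397 in the chrVI set and −0.0647 in the chrX set, where RAD52 was covered, again in opposite directions and not tested. Different shares of reads that are not Okazaki fragments may account for part of this, since removing the minor-strand share of one-sided bins left −0.0232 (−0.0278 to −0.0167) and 0.0199 (0.0158 to 0.0244) for the repeat, part of each difference, so that background reads and an effect of the strains cannot be told apart there. For the RAD52 label it left 0.0295 (0.0201 to 0.0423) in the chrVI set and −0.0419 (−0.0507 to −0.0360) in the chrX set, most of each difference. If the share of such reads was the same at all origins of a library, this argued against them as the whole cause, in the chrVI set by a narrow margin. The intervals resample origins with that share held fixed, so they carry neither the error of the correction nor that between cultures. Shorter reads of the chrX control cannot be told apart from its strain either, since chrX (AT)34 and the library labelled rad52Δ, which have reads of 1 length, also differed, by −0.0820 between their median efficiencies. The 155 origins with a mean efficiency over 0.5 and the 127 others changed unequally. From control to (AT)34 their medians were −0.0684 and −0.0083 in the chrVI set, and 0.0439 and 0.0284 in the chrX set. For the RAD52 label they were 0.0283 and 0.0675 in the chrVI set, and −0.0875 and −0.0025 in the chrX set.

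In the library labelled rad52Δ (AT)34 chrX, forks crossed FAB1 on chromosome VI rightward. Too few reads were argued against by a log2 coverage of 0.37, close to the 0.38 to 0.57 of the other libraries. Reads of both strands pull fork direction towards 0 and not past it, and it stood at 0.370 against −0.764 to −0.655. Loss of RAD52 would have to turn the same forks in chrVI (AT)34 rad52Δ, where the value was −0.764, below the −0.751 to −0.655 of the RAD52+ libraries. What differs in this strain around FAB1 was not tested.

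In chrVI (AT)34, fork direction turned around ADE1 on chromosome I. Too few reads were argued against by a log2 coverage of 1.32, above the 0.63 to 0.87 of the others. An effect of the repeat in both sets was argued against by chrX (AT)34, at −0.520 below both controls at −0.423 and −0.347, while chrVI (AT)34 stood at 0.620. A rearranged segment of this strain may be the cause: fork direction dropped by 1.23 within 2 kb at the right edge, against 0.541 to 0.729 near ADE1 in the other libraries. That drop ranked at 3 in its library, so a rearrangement cannot be told apart from a local change in origin use. Coverage of ADE1 was also raised in this library, at 4.90 of the median gene against 1.35 to 2.28 in the others. Whether the raised coverage and the turned fork direction share a cause, such as extra copies of this sequence, was not tested.

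Mitochondrial DNA, which the comparisons did not use, took 0.777% of coverage in chrVI (AT)34 rad52Δ, above the 0.376% of its control. It took 0.521% in the library labelled rad52Δ (AT)34 chrX, in which RAD52 was covered, above the 0.475% of its control. The (AT)34 libraries lay below their controls, at 0.292% in the chrVI set and 0.181% in the chrX set.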

How the results depend on the processing

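The tests without each library were planned, and those named as added were chosen after the data had been seen. Of 157 alternatives, 104 left the result inside its interval, or its count of calls near the main count. Of the rest, 22 weakened it, 19 strengthened it, 7 moved it and 5 turned it. For fork direction, at the chrX site and at the largest differences on chromosome VI, 60 of 66 left it inside its interval. The cause was not tested for any of the following unless given. In CDC4 the difference of −0.174 turned to 0.0167 with the mean of 100 bp values. At RIM15 windows of 10 kb gave 0.198 from (AT)34 and 0.281 from the control. At the chrX site the library labelled rad52Δ gave −0.104 from the control in 2 kb windows. Left of ARS1019 (added) it gave 0.0062 from (AT)34, which turned the direction, and 0.0296 from the control. The lowest profile correlation was 0.957 in 5 kb and 0.924 in 200 bp bins, and 14 feature lists lay outside the random range with 500 bp on each side, with all 9 among them. With flanks of 1 to 3 kb 8 lay outside, with 6 of the 9 among them.

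Origins called for the RAD52 label were 2 without trend and robust fitting, 6 at a common amplitude (added), and 0 to 102 without each library in turn. Without 1 library a strain type holds only 1, so that the others supply its spread and these counts show only that the fit is unstable. For the repeat they were 0 to 83 without each library. Between the sets they were 15 on the logit scale, 132 at a common amplitude (added), and 0 to 130 without each library. Most of the 130 without chrVI (AT)34, and of the 130 without chrX (AT)34, were lower in the chrX set, which turned the direction. Of 10 splits of the 6 libraries into 3 and 3, 1 gave as many origins and 1 as many genes as the sets, the sets themselves; 10 splits are too few for a share under 0.05. The sets gave 64 origins and 2093 genes, and the highest other split gave 51 and 1.

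Genes called for the RAD52 label were 0 with a pseudocount of 0.5, 11 with 0.01, 10 without low genes, 0 with quantile scaling, 1 with total coverage, 0 without trend and robust fitting, 0 without the set term, and 0 to 277 without each library. For the repeat, which was not planned for genes, they were 10 with a pseudocount of 0.01, 2 without low genes, 0 with quantile scaling, 0 without trend and robust fitting, 0 without the set term and 0 to 52 without each library. Between the sets quantile scaling gave 1532, of which 757 were higher and 775 lower, so that the larger share turned, and 808 to 2085 passed without each library. Lists called fell to 0 in each comparison with an estimated correlation in camera, from 1 for the RAD52 label, 1 for the repeat and 2 between the sets. With quantile scaling the engineered loci were called for the RAD52 label (camera adjusted p = 0.0417). Not run were a shift of the chrVI position, which was not found, and other lengths of natural repeats. No paired analysis was possible because the labels give no 2 replicate numbers that strains share; the chromosome set was already a term of the fits. Coverage with 1 library per strain limits every value at a single site.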

Other observations

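The tests in this part were chosen after the results had been seen. Gene coverage followed the distance from the nearest efficient origin, and did so more steeply in the chrVI set. For the 1504 genes under 10 kb from an origin with an efficiency over 0.5, the median coverage was 1.34, 1.26 and 1.17 of the median gene in the chrVI control, (AT)34 and rad52Δ libraries, and 1.08, 1.14 and 1.05 in their chrX counterparts. For the 1944 genes over 30 kb away it was 0.645, 0.742 and 0.799 in the chrVI set and 0.896, 0.868 and 0.926 in the chrX set. The median difference between the sets was −0.17 (log2) under 10 kb, −0.06 over 1429 genes at 10 to 20 kb, 0.00 over 1081 genes at 20 to 30 kb and 0.23 over 30 kb, where 1468 genes were higher in the chrX set. No test was run on this gradient.

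Repeated arrays differed between the libraries. Coverage of the CUP1 copper-resistance array on chromosome VIII, taken over only 500 bp beside CUP1-2, was 0.257 of the median in chrVI (AT)34 and 0.419 in the library labelled rad52Δ (AT)34 chrX, against 1.20 in the chrVI control, 2.64 in chrVI (AT)34 rad52Δ, 1.45 in the chrX control and 1.79 in chrX (AT)34. The drop of fork direction from the left to the right flank of the array was 0.727 and 0.315 in the first pair and 1.40, 1.12, 1.21 and 1.33 in the others. No relation between both measures was tested. Coverage of the rDNA was 2.21 in chrVI (AT)34 and 4.21 to 5.85 in the others.

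Regions of at least 3 bins that lay over 0.5 from the median of the other 5 libraries were most frequent in the chrVI control, with 10 regions and 75 kb. There were 6 (27 kb) in chrVI (AT)34, 5 (49 kb) in the library labelled rad52Δ (AT)34 chrX, 3 (12 kb) in chrVI (AT)34 rad52Δ and 1 each in the chrX control (3 kb) and chrX (AT)34 (5 kb). In the library labelled rad52Δ (AT)34 chrX, right of the rDNA, between 490.5 and 496.5 kb on chromosome XII, fork direction was −0.0720 against −0.807 to −0.560. On chromosome XIII the segment between the Ty elements YML045W and YML039W, next to the region with RAD52, had 1.65 times the coverage of the next segment, against 0.872 to 0.955 in the other libraries.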
